A study of Mus musculus with 6 samples.

How the data were processed

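The data are bulk RNA-seq read counts of 6 libraries of mouse lung interstitial macrophages, 3 from mice given PBS and 3 from mice given WGP, a β-glucan. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, lungs were digested to single cells, interstitial macrophages were obtained with fluorochrome-labelled antibodies, RNA was extracted from cells kept in TRIzol, and libraries were made with a NuGEN Universal Plus mRNA-Seq kit after polyA selection. The antibodies and the gate are not named there. The counts per gene were made by the authors before they deposited them, and per the submitters' processing notes HTSeq 0.10.0 and FastQC 0.10.1 and the genome builds GRCm38 and mm10 were used. The aligner, the annotation and the strand setting of the counting are not given in the sources used here. The values are whole numbers that sum to different totals in each library, so they were analysed as raw counts.

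The table held 21965 genes, of which 6462 had no count in any library. The GENCODE M21 annotation of GRCm38 matched 21939 of the Ensembl identifiers (99.9%), 99.7% of them protein-coding, and supplied symbols and coordinates. Where several identifiers shared a symbol, the one with the highest total count kept the plain symbol. Mitochondrially encoded genes and some genes of the lists, 1 of them among the genes fixed by name, were not analysed here. Without a stated strand setting, reads of genes whose exons overlap cannot be told apart. Of the changed genes 1345 (35.3%) overlapped an exon of another gene, on either strand, among them Plppr3, Prtn3, Fam117a, Lrrc20, Hacd4, Plet1, Ch25h and Syne2. Reads of near-identical family members (Ly6c1 and Ly6c2, Bcl2a1, Ifitm, Gbp and H2 genes, ribosomal protein genes and their pseudogenes) can be shared or lost in counting, so their values are less certain.

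Totals ran from 18254678 to 20346517 counts per library. A gene with no count in a library has an upper limit of 3 counts there. Counts were simulated for 12305 genes from the means over all libraries, the fitted dispersions and the library sizes, with 200 genes changed. The test recovered 33 of 67 genes changed 1.5-fold (49.3%), 37 of 66 changed 2-fold (56.1%) and 57 of 64 changed 4-fold (89.1%). It also called 14 of 12105 unchanged genes. These 14 false calls were a larger share of the simulated calls than the adjusted p threshold of 0.05 aims at. The simulation changed 200 genes, where 3809 were called in the data, so its share of false calls does not give that of the data. Replicates were compared by a chi-square of their counts, which gave 13.5 to 24.8 per degree of freedom, so no library repeated another.

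WGP was compared with PBS in edgeR 4.0.16 under R 4.3.3 (filterByExpr, TMM normalisation, estimateDisp and glmQLFit with robust = TRUE, quasi-likelihood F test, two-sided) with Benjamini-Hochberg adjustment over the 12305 genes kept and a threshold of 0.05. The biological coefficient of variation was 0.18. The SE of a log2 fold change was its size divided by the square root of F. CPM are TMM-normalised, and correlations and principal components used log2 CPM with a prior count of 2. No exact test of 3 against 3 values can give a two-sided p below 0.1, so single genes were tested only in models fitted across all genes.

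Before the data were examined, 47 gene lists were fixed: markers of the sorted cell and of other lung and blood cells, immune functions, metabolism and general cell state. The 45 lists with at least 4 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01, Benjamini-Hochberg over lists), and again with an estimated correlation and with fry. By camera 23 lists passed (9 higher and 14 lower), with an estimated correlation 0 passed (smallest adjusted p = 0.377), and by fry's directional test 24 passed. Genes were named by a rule fixed at the same time: the 10 highest and 10 lowest log2 fold changes among genes with adjusted p under 0.05, mean CPM of at least 5 and no overlap between the groups, passing over predicted models and pseudogenes (40 passed over, 3189 eligible), the 5 smallest p-values in each direction, up to 4 members of each list by smallest p, and fixed names from the design. Some genes that met this rule are not reported here. Chosen after their values were seen, to complete counts of 5 or fewer, were Mrc1, Ms4a7, Clec4n, Tlr4, Tlr2, Hmox1, Srxn1, Cat, Prdx1, Ccl9, Tgfb1, Scd2, Acaca, Srebf1, Ppard, Icam1, Nfkbie, Birc3, Nfkb1, Cd40, Sirpa, Tnfsf9, Cd86, Slc16a1, Pfkfb3, Rpe, Prps1, Atp5b, Suclg2, Aco1, Slc11a1, Asl, Lrp1, Tet2, Kat5, Kdm6a, Kdm5c, Mtfr1l, Mmp13, Timp2 and Itgb1.

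Alternatives fixed before the data were examined were other scalings (size factors of DESeq2, upper quartile, library sizes alone), other low-count filters (none, or CPM of at least 1 in 3 libraries), DESeq2 1.42.0, limma-voom with and without quality weights, glmQLFit without robust estimation, other thresholds (adjusted p under 0.1, or under 0.05 with a 2-fold change), the replicate number as a block, and leaving out each library. Chosen after the data were seen were a Y-linked covariate, leaving out the PBS libraries with low Y-linked levels, removal of length and GC trends and thinning to the smallest total.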

Results

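RNA sequencing of polyA-selected transcripts was done on interstitial macrophages, the macrophages of the lung tissue between the alveoli and around the airways, sorted with antibodies from digested lungs of C57Bl/6 mice. The mice had received β-glucan, a glucose polymer of yeast and fungal cell walls (the preparation labelled WGP), or phosphate-buffered saline (PBS) into the peritoneum. The WGP dose was 1 mg, the treatment is given as lasting 6 days, and the lungs were taken on day 7. Each group had 3 libraries, numbered 1 to 3, and the labels do not say whether a library came from 1 mouse or from several. The p-values therefore measure only the spread between these libraries, which may be technical among the WGP libraries. In PBS replicates 1, 2 and 3 Y-linked transcripts summed to 112, 179 and 9.79 CPM, which repeats of the same RNA would not give. The comparison of WGP with PBS asks how treatment with an inducer of trained immunity, a lasting change in the responses of innate immune cells, altered transcript levels in lung interstitial macrophages before metastases form.

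The libraries held 19549252, 18910786 and 20346517 counts after PBS and 18254678, 19451407 and 19325986 counts after WGP. At least 1 count was seen for 14065 ± 148 genes after PBS and for 13210 ± 209 genes after WGP (mean ± SD, n = 3). The 10 most abundant genes took between 6.21% and 7.00% of the counts of a library. Across genes, log2 CPM correlated with r between 0.964 and 0.983 within the groups and between 0.921 and 0.954 across them. The first principal component, with 64.7% of the variance, separated the WGP from the PBS libraries, and the second, with 13.8%, set WGP replicate 1 apart from WGP replicates 2 and 3. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and those of gene lists are from limma's camera test with Benjamini-Hochberg adjustment over 45 lists. Log2 fold changes are WGP over PBS with their SE, and levels are TMM-normalised read counts (CPM), mean ± SD with n = 3.

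After WGP, transcripts of classical monocytes and of the interferon response were higher, and transcripts of alveolar macrophages, of epithelial and endothelial cells and of the heat shock response were lower. These calls of gene lists were lost when the correlation between members was estimated, where the smallest adjusted p of all 45 lists was 0.377. Ccr2, the chemokine receptor that brings monocytes out of the bone marrow, rose from 248 ± 48.3 to 1031 ± 46.3 CPM, a log2 fold change of 2.06 ± 0.13 (adjusted p = 1.8e-05). Chil3, a chitinase-like protein abundant in alveolar macrophages, fell from 3478 ± 744 to 751 ± 64.4 CPM, a log2 fold change of -2.21 ± 0.16 (adjusted p = 8.4e-05). Tnf fell from 88.4 ± 9.63 to 32.7 ± 4.77 CPM (log2 fold change -1.43 ± 0.12, adjusted p = 3.7e-05), whereas Il1b, at 1570 ± 383 and 1774 ± 604 CPM, did not pass the test (log2 fold change 0.18 ± 0.32, adjusted p = 0.73).

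Of 12305 genes tested, 3809 changed, 1874 of them higher and 1935 lower after WGP. Changes of at least 2-fold were mostly decreases, with 1134 such genes lower and 163 higher. These were 906 and 217 with the Y-linked level as a covariate and 517 and 172 without PBS replicates 1 and 3, alternatives chosen after the data were seen. The 3 WGP libraries lay wholly above or below the 3 PBS libraries for 5918 genes, which is 48.1% of those tested, where chance gives 10%. With library sizes alone as the scaling, 1236 genes were higher and 2460 lower. Of the changed genes 33.4% in place of 49.2% were then higher, and the median log2 fold change of all tested genes lay at -0.12 in place of -0.02. Without PBS replicate 1 the number of changed genes was 2491 (1202 higher and 1289 lower). Without both PBS replicates 1 and 3, which had the lowest levels of Y-linked transcripts, it was 1820.

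**Figure D1:**
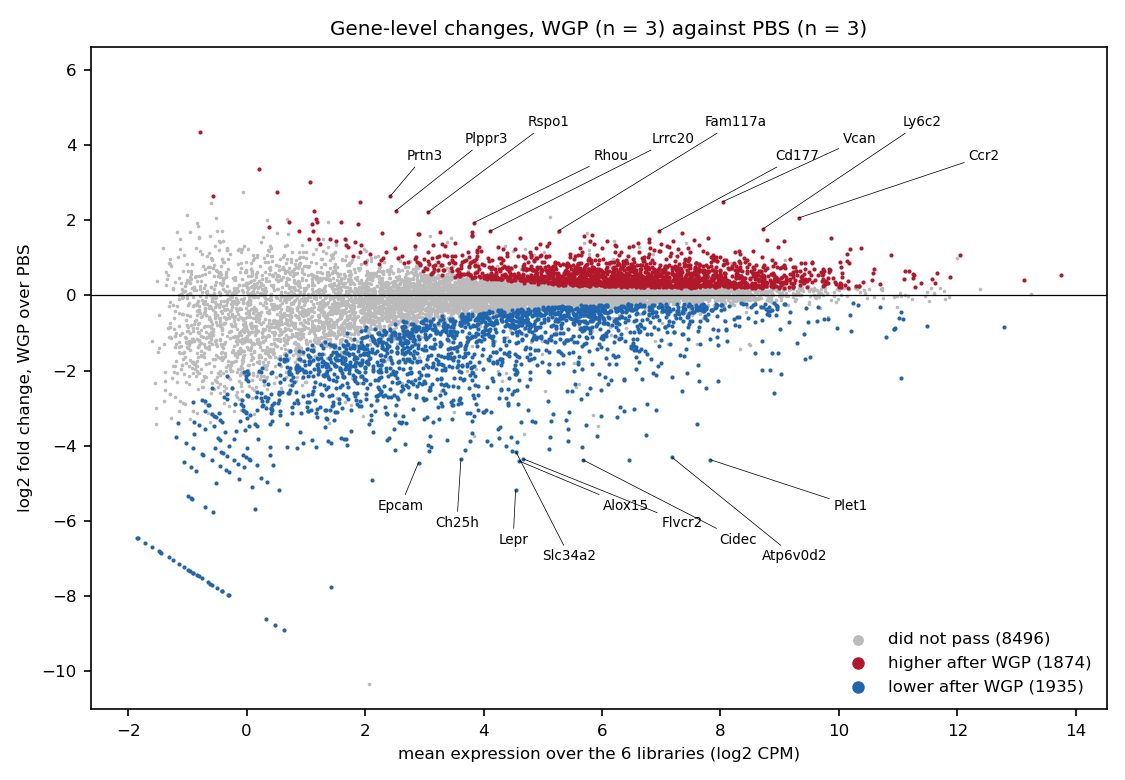
Log2 fold change, WGP over PBS, of the 12305 tested genes against mean expression over the 6 libraries (log2 CPM). Each point is 1 gene, red for the 1874 genes higher and blue for the 1935 genes lower after WGP and grey for the rest. Labels mark 10 higher and 9 lower genes of the naming rule. The straight run of points at the lower left holds genes with no count in a group, whose fitted fold change depends on the prior count.

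Among the genes with the highest fold change, Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557) and Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970) had the highest levels after WGP apart from Vcan. Ly6c2, which encodes the Ly6C antigen of classical monocytes, rose from 191 ± 59.5 to 649 ± 24.6 CPM (log2 fold change 1.76 ± 0.22, adjusted p = 0.0024). Prtn3, which encodes the granule protease proteinase 3, had the highest fold change (2.63 ± 0.36, adjusted p = 0.00044) at only 1.49 ± 0.47 and 9.24 ± 2.95 CPM. Its exons overlap those of Plppr3 on the other strand (log2 fold change 2.25 ± 0.38), and the reads of both genes cannot be told apart unless they were counted by strand. The others were Rspo1 (2.20 ± 0.27), Rhou (1.93 ± 0.16), Fam117a (1.72 ± 0.10), Cd177 (1.71 ± 0.13) and Lrrc20 (1.70 ± 0.18). Vcan, which encodes the matrix proteoglycan versican, was among them too (2.49 ± 0.54, adjusted p = 0.030). Among the genes that rose with the smallest p-values were Fam117a, Nhsl2 (1.64 ± 0.09), Cers6 (1.09 ± 0.07) and Hacd4 (1.19 ± 0.08), with adjusted p between 8.6e-06 and 1.1e-05.

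The largest decreases among well-expressed genes included those of Lepr, the leptin receptor (-5.18 ± 0.89), the epithelial adhesion molecule Epcam (-4.45 ± 0.59), the lipoxygenase Alox15 (-4.41 ± 0.33), Plet1 (-4.37 ± 0.96) and the lipid droplet protein Cidec (-4.37 ± 0.80). Next came the cholesterol hydroxylase Ch25h (-4.36 ± 0.67), Flvcr2 (-4.35 ± 0.79), the vacuolar ATPase subunit Atp6v0d2 (-4.31 ± 0.84) and the phosphate transporter Slc34a2 (-4.15 ± 0.82). Plet1, at 435 ± 163 CPM after PBS and 20.9 ± 17.7 CPM after WGP, and Atp6v0d2, at 277 ± 78.9 and 13.9 ± 13.1 CPM, were the most abundant of these in PBS libraries. The smallest p-values among genes that fell belonged to the junction protein Jup (-1.39 ± 0.07), the unconventional myosin Myo7a (-1.56 ± 0.08), the epithelial cadherin Cdh1 (-3.06 ± 0.16), Ccl17 (-2.88 ± 0.17) and the nuclear envelope protein Syne2 (-1.64 ± 0.10), with adjusted p between 7.5e-06 and 9.0e-06. Cdh1 (ENSMUSG00000000303, chromosome 8, 106603351 to 106670246) fell from 29.3 ± 2.49 to 3.52 ± 0.40 CPM, and Jup (ENSMUSG00000001552, chromosome 11, 100368958 to 100397763) from 130 ± 3.20 to 49.6 ± 0.78 CPM.

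Several of these calls were lost when 1 of several libraries was left out, while the log2 fold changes then lay between -5.10 and -4.09 for the lower genes, between 2.29 and 2.81 for Vcan and between 0.76 and 0.84 for Cx3cr1. Leaving out PBS replicate 1 ended the calls of Vcan, Lepr, Plet1, Cidec, Flvcr2, Atp6v0d2, Slc34a2 and Cx3cr1 (adjusted p between 0.051 and 0.105). Leaving out WGP replicate 3 ended the same 8 calls (0.052 to 0.102). Leaving out PBS replicate 2 ended those of Vcan, Plet1, Cidec, Flvcr2 and Atp6v0d2 (0.056 to 0.085). Without PBS replicate 3 those of Vcan and Plet1 were lost (0.107 and 0.062), and without WGP replicate 2 those of Slc34a2 and Cx3cr1 (0.067 and 0.055).

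Classical monocyte markers rose together. Of 15 tested, 12 rose and 3 did not pass, and 13 rose when adjusted over the list alone. The median log2 fold change was 1.34 (camera adjusted p = 4.4e-08; adjusted p = 0.377 with an estimated correlation). Besides Ccr2 and Ly6c2 they included Ifitm6 (log2 fold change 1.52 ± 0.12, adjusted p = 5.3e-05) and Sirpb1c (0.75 ± 0.08, adjusted p = 8.3e-05). Nonclassical monocyte markers did not pass as a list, with 1 of 14 higher (Pou2f2), 2 lower (Fabp4 and Cd36) and a median of -0.02 (adjusted p = 0.64). Without PBS replicate 3 or WGP replicate 1, 3 rose and the median was 0.06. The counts adjusted over the list alone were the same. Neutrophil markers did not pass either (adjusted p = 0.72). Of 16 tested, also adjusted over the list alone, 2 rose, Cd177 and Mmp8 (1.17 ± 0.25, adjusted p = 0.020). Mmp8 no longer passed without PBS replicate 1 (adjusted p = 0.077) or PBS replicate 3 (0.056), and 3 neutrophil genes fell without PBS replicate 3. The list's median of -0.12 and mean of -0.39 had the opposite sign to its test.

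Alveolar macrophage markers had the lowest median of the lists that passed, at -3.34. Of 20 tested, 17 fell and 3 did not pass, and 19 fell when adjusted over the list alone (camera adjusted p = 1.0e-08; adjusted p = 0.430 with an estimated correlation). The number that fell was 9 without PBS replicate 1 or 2 and 10 without WGP replicate 3, with medians from -3.32 to -3.21. The median of the epithelial list was lower than this list's without PBS replicate 1 (-3.37) or WGP replicate 3 (-3.79). The integrin gene Itgax fell from 741 ± 49.6 to 257 ± 36.5 CPM (log2 fold change -1.53 ± 0.11, adjusted p = 1.4e-05), the ribonuclease Ear2 from 581 ± 85.5 to 250 ± 17.9 CPM (-1.21 ± 0.11). Pparg, the transcription factor needed for alveolar macrophage differentiation, fell from 117 ± 18.1 to 50.7 ± 4.70 CPM (-1.21 ± 0.12). The summed level of the 20 genes was 8689 ± 1728 CPM after PBS and 2041 ± 202 CPM after WGP. Of the interstitial macrophage markers, 3 of 22 were higher, 5 lower, 14 not passed, the same counts adjusted over the list alone and a median of -0.56 (adjusted p = 0.024; adjusted p = 0.635 with an estimated correlation). The Fc receptor gene Fcgr1 rose (1.03 ± 0.11, adjusted p = 0.00012). The phagocytic receptor gene Mertk (-3.01 ± 0.21, adjusted p = 0.00014), Mrc1 (-2.08 ± 0.33), Ms4a7 (-1.23 ± 0.21), Apoe (-0.63 ± 0.11) and Tmem176a (-0.46 ± 0.08) fell. Without WGP replicate 1, 13 fell and the median was -0.95, 8 fell without WGP replicate 3, and 10, 12 and 11 fell with DESeq2, with limma-voom and without robust estimation. The list's call was lost without PBS replicate 1 (adjusted p = 0.053), PBS replicate 3 (0.099), WGP replicate 2 (0.065) or WGP replicate 3 (0.056). Csf1r, the receptor for the macrophage growth factor, rose by a log2 fold change of 0.33 ± 0.08 (adjusted p = 0.0071), and Cx3cr1 by 0.83 ± 0.20 (adjusted p = 0.021).

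Markers of non-immune lung cells were lower after WGP. Of 14 epithelial genes 10 fell, 1 rose and 3 did not pass, or 12 fell and 1 rose when adjusted over the list alone. Their median was -3.24 (adjusted p = 0.00020; adjusted p = 0.470 with an estimated correlation). A total of 5 fell without PBS replicate 1, and 6 fell without PBS replicate 2, PBS replicate 3, WGP replicate 2 or WGP replicate 3. The number was 6 with the Y-linked level as a covariate and 3 without PBS replicates 1 and 3, where Krt18 did not pass (0.056), both chosen after the data were seen. Epcam and Cdh1 were among those that fell, the keratin gene Krt18 fell from 2.61 ± 0.39 to 0.11 ± 0.09 CPM, and Hopx was the gene that rose (0.99 ± 0.09, adjusted p = 6.0e-05). Of 16 endothelial genes 12 fell, or 13 when adjusted over the list alone, with a median of -1.54 (adjusted p = 5.9e-06; adjusted p = 0.377 with an estimated correlation). Pecam1 (-1.45 ± 0.13), Vwf (-1.50 ± 0.18) and Tek (-2.03 ± 0.28) were among them. Fibroblast and smooth muscle genes had a median of -1.34 (adjusted p = 0.011; adjusted p = 0.607 with an estimated correlation). Of the 15 genes 3, both over all genes and adjusted over the list alone, fell, namely Inmt, Mfap4 and Mgp, while 6 fell without WGP replicate 1 or with limma-voom. The summed levels were 550 ± 212 and 131 ± 29.2 CPM for the epithelial, 609 ± 4.94 and 288 ± 52.2 CPM for the endothelial and 460 ± 43.4 and 369 ± 52.8 CPM for the fibroblast list, after PBS and WGP. In PBS replicates 1, 2 and 3 the epithelial sum was 479, 788 and 382 CPM, in the order of the alveolar macrophage sum (8915, 10292 and 6859 CPM). In WGP replicates 1, 2 and 3 the epithelial sum was 98.4, 139 and 155 CPM and the alveolar macrophage sum 1896, 2271 and 1955 CPM. Both were lowest in replicate 1, the WGP library furthest from the PBS libraries on the first principal component. Replicates 2 and 3 stood in opposite order in the 2 sums. The endothelial sum was 614, 604 and 610 CPM in the same PBS libraries. Which cells held the epithelial transcripts cannot be told from these bulk libraries.

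Most single genes of the lymphoid and dendritic lists did not pass. Summed levels after PBS and WGP were 260 ± 58.2 and 102 ± 60.3 CPM for T and NK cell markers and 176 ± 18.8 and 104 ± 39.3 CPM for B cell markers. Of 17 T and NK cell genes 2 fell, Il7r (-1.61 ± 0.26, adjusted p = 0.0012) and Klrd1 (-1.36 ± 0.40, adjusted p = 0.024), or 1 when adjusted over the list alone. The list did not pass (median -1.03, adjusted p = 0.057), and its median was -0.51 without WGP replicate 1 and -2.09 without WGP replicate 2. It did pass without PBS replicate 2 (0.047), WGP replicate 2 (0.018) or WGP replicate 3 (0.022). The call of Klrd1 was lost without any 1 library other than WGP replicate 3 (0.052 to 0.082). Of 11 B cell genes, also adjusted over the list alone, only Cd22 fell (-1.15 ± 0.09, adjusted p = 1.8e-05), against 3 genes without WGP replicate 2, and the list did not pass (adjusted p = 0.15), except without WGP replicate 2 (0.027). Of 18 dendritic cell genes 6 fell, among them Cd209a (-1.49 ± 0.11), Zbtb46 (-0.95 ± 0.23) and Ccl22 (-1.84 ± 0.32), and Irf8 rose (1.03 ± 0.14). With the Y-linked level as a covariate 1 gene fell, and Zbtb46 (0.080) and Ccl22 (0.062) did not pass, and 1 fell without PBS replicates 1 and 3, alternatives chosen after the data were seen. The counts with all libraries were the same adjusted over the list alone. That list's adjusted p of 0.047 (adjusted p = 0.635 with an estimated correlation) went above 0.05 without PBS replicate 1 (0.059), PBS replicate 3 (0.183) or WGP replicate 1 (0.067), with upper quartile scaling (0.054) or library sizes alone (0.058) and with no filter on low counts (0.053), and likewise with the Y-linked covariate (0.315), without PBS replicates 1 and 3 (0.472) or with length and GC trends removed (0.054), chosen after the data were seen. The dendritic list's call was also lost with the replicate number as a block, and 6 of 16 refits kept it. None of the 8 erythroid and platelet genes passed, over all genes or adjusted over the list alone (list adjusted p = 0.54; the highest single-gene evidence was Ppbp, -2.23 ± 0.88, adjusted p = 0.077). Without WGP replicate 1, 3 of them rose and 1 fell. That list's median of 0.07 differed in sign from its mean of -0.38 and from its test.

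**Figure D2:**
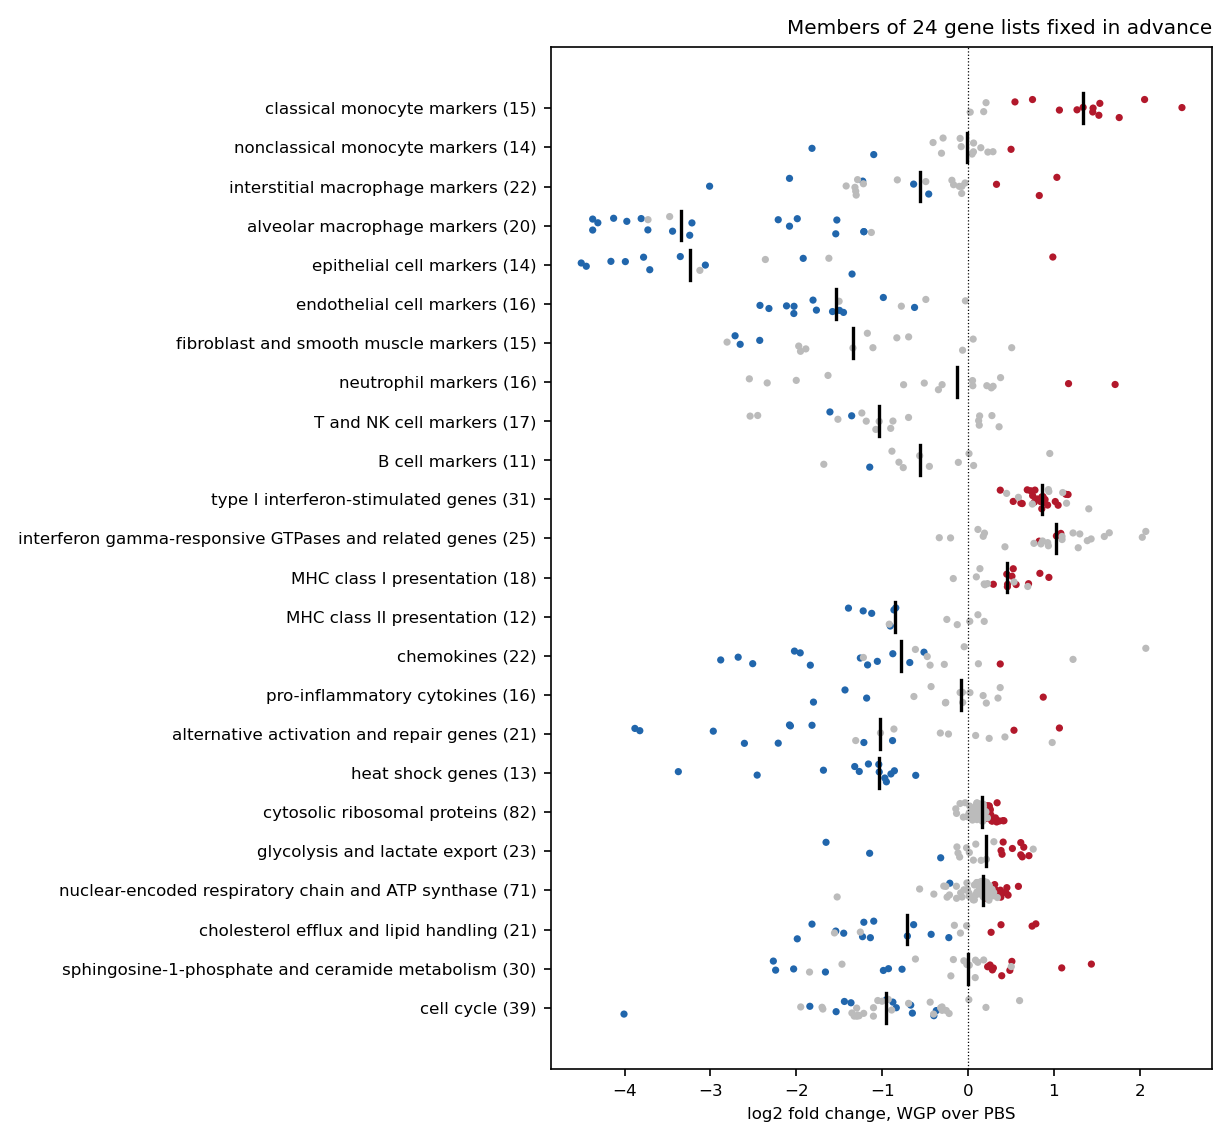
Log2 fold change, WGP over PBS, of the members of 24 gene lists. Each point is 1 gene, red for genes that rose, blue for genes that fell and grey for genes that did not pass, with the list's median as a black bar and the number of members tested in parentheses. Medians ran from -3.34 for alveolar macrophage markers to 1.34 for classical monocyte markers.

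Type I interferon-stimulated genes rose, 23 of 31 over all genes and 28 adjusted over the list alone, and none fell. Their median was 0.86 (adjusted p = 6.4e-10; adjusted p = 0.470 with an estimated correlation). The synthetase gene Oas3 rose from 161 ± 18.4 to 326 ± 42.9 CPM (log2 fold change 1.02 ± 0.11, adjusted p = 0.00018). Ifitm3, which restricts virus entry, rose from 817 ± 127 to 1481 ± 47.6 CPM (0.86 ± 0.10, adjusted p = 0.00020), and the RNA sensor gene Ifih1 from 78.6 ± 7.16 to 132 ± 11.8 CPM (0.75 ± 0.09, adjusted p = 0.00023). Interferon gamma-responsive genes had a median of 1.03 (adjusted p = 0.0015; adjusted p = 0.635 with an estimated correlation). Of 25 genes 3 rose, also adjusted over the list alone. Without WGP replicate 2 the median was 0.35, and 7 rose and 1 fell, and 6 rose without WGP replicate 1. With DESeq2 11 rose, with limma-voom 10 and without robust estimation 11. The 3 genes were Irf8, Gbp9 (0.83 ± 0.15, adjusted p = 0.0050) and Irgm2 (1.08 ± 0.23, adjusted p = 0.013). The call of Irgm2 was lost without PBS replicate 1 (0.059), 2 (0.061) or 3 (0.054). Classical monocyte markers rose in the same libraries.

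The 2 classes of antigen presentation genes moved apart. Of 18 MHC class I genes 10 rose and none fell, 11 when adjusted over the list alone. The median was 0.46 (adjusted p = 0.00039; adjusted p = 0.607 with an estimated correlation). Among the genes that rose were the proteasome activator Psme1 (0.46 ± 0.09), H2-T22 (0.70 ± 0.13), the peptide-loading chaperone Tapbp (0.45 ± 0.09) and the immunoproteasome subunit Psmb10 (0.51 ± 0.11). When PBS replicate 1 was left out, 4 of the 18 rose, and 6 without PBS replicate 2 or WGP replicate 3. With library sizes alone as the scaling 4 rose, and with upper quartile scaling 5. Of 12 MHC class II genes 6 fell and none rose, 7 when adjusted over the list alone. The median was -0.85 (adjusted p = 0.011; adjusted p = 0.635 with an estimated correlation). The invariant chain gene Cd74 fell from 9073 ± 457 to 5063 ± 910 CPM (-0.84 ± 0.12, adjusted p = 0.00065). H2-Aa fell from 2537 ± 144 to 1395 ± 292 CPM (-0.86 ± 0.14, adjusted p = 0.0021) and H2-Eb1 from 2428 ± 76.5 to 1115 ± 270 CPM (-1.12 ± 0.16, adjusted p = 0.0018). The class II list no longer passed with the Y-linked level as a covariate (adjusted p = 0.055) or without PBS replicates 1 and 3 (0.099), alternatives chosen after the data were seen. In the latter 1 of the 12 genes fell, and Cd74 (0.070), H2-Aa (0.142) and H2-Eb1 (0.131) did not pass. The summed alveolar macrophage markers, 8689 ± 1728 and 2041 ± 202 CPM, fell in the same libraries. After PBS and WGP the summed interstitial macrophage markers were at 10647 ± 727 and 8391 ± 784 CPM. The summed dendritic cell markers were at 2815 ± 183 and 2532 ± 151 CPM. Which cells held the class II transcripts was not tested. Co-stimulatory and co-inhibitory genes did not pass as a list (adjusted p = 0.47). Of 12 genes 4 rose, Cd40 (1.24 ± 0.29), Vsir (0.89 ± 0.07), Lgals9 (0.61 ± 0.08) and Sirpa (0.24 ± 0.07). Another 4 fell, Tnfsf9 (-1.04 ± 0.23), Icosl (-0.76 ± 0.09), Havcr2 (-0.68 ± 0.08) and Cd86 (-0.51 ± 0.08), the same counts as adjusted over the list alone. Cd40 did not pass without PBS replicate 1 (0.073) or 2 (0.071), nor Sirpa without PBS replicate 1, PBS replicate 2 or WGP replicate 2 (0.051 to 0.079). The call of Sirpa was also lost with library sizes alone (log2 fold change 0.13, adjusted p = 0.136) or upper quartile scaling (0.071).

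Chemokine genes fell, 12 of 22 lower and 1 higher over all genes and adjusted over the list alone. The median was -0.78 (adjusted p = 0.00070; adjusted p = 0.377 with an estimated correlation). The gene that rose was Ccl9 (0.38 ± 0.09), though not without PBS replicate 1 (adjusted p = 0.059). Ccl22 and Pf4 are also cell-type markers, and of the 20 other genes 11 fell and 1 rose, with a median of -0.65. The summed alveolar macrophage markers fell in the same libraries, from 8689 ± 1728 to 2041 ± 202 CPM. Interstitial macrophage markers summed to 10647 ± 727 and 8391 ± 784 CPM after PBS and WGP, and dendritic cell markers to 2815 ± 183 and 2532 ± 151 CPM. Without PBS replicates 1 and 3, chosen after the data were seen, 7 chemokine genes fell, and Cxcl16 did not pass (0.086). Ccl17 fell from 42.2 ± 1.92 to 5.72 ± 1.26 CPM, Ccl7 from 14.5 ± 1.93 to 2.55 ± 0.70 CPM and Cxcl16 from 152 ± 8.18 to 39.2 ± 13.3 CPM, with adjusted p of 9.0e-06, 7.6e-05 and 0.0018. Pro-inflammatory cytokine genes did not pass as a list (median -0.08, adjusted p = 0.48). Of 16 genes, also adjusted over the list alone, 3 fell and 1 rose. Those that fell were Tnf, Il18 (-1.18 ± 0.13, adjusted p = 0.00010) and Il1a (-1.80 ± 0.21, adjusted p = 0.00017). Il27 rose (0.88 ± 0.23, adjusted p = 0.015), though not without PBS replicate 1 (0.054), PBS replicate 2 (0.058) or WGP replicate 2 (0.057). Il6 was low in both groups, at 5.35 ± 2.66 and 4.46 ± 1.28 CPM, and did not pass (-0.26 ± 0.39, adjusted p = 0.65). Targets and feedback regulators of NF-kB went both ways, with 5 of 21 higher, Bcl3 (1.16 ± 0.10), Icam1 (0.54 ± 0.13), Nfkbie (0.53 ± 0.08), Birc3 (0.48 ± 0.08) and Nfkb1 (0.24 ± 0.07). The 6 lower genes included the near-identical Bcl2a1a, Bcl2a1b and Bcl2a1d, whose reads can be shared. Without PBS replicate 2 or WGP replicate 1, 3 fell. The counts adjusted over the list alone were the same, and the list's median of 0.12 and its mean of -0.01 differed in sign (adjusted p = 0.52). The call of Icam1 was lost without PBS replicate 1 (0.074) or 2 (0.072), and that of Nfkb1 without PBS replicate 1, PBS replicate 2, WGP replicate 2 or WGP replicate 3 (0.055 to 0.103). Nfkb1 also did not pass with library sizes alone (log2 fold change 0.14, adjusted p = 0.160) or upper quartile scaling (0.090).

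Genes of alternative activation and repair fell more often than they rose, 10 of 21 lower and 2 higher over all genes and adjusted over the list alone. The median was -1.02 (adjusted p = 0.012; adjusted p = 0.377 with an estimated correlation). Osteopontin, Spp1, fell from 80.5 ± 24.3 to 5.45 ± 2.05 CPM (log2 fold change -3.88 ± 0.36) and the lectin gene Mgl2 from 279 ± 16.4 to 66.6 ± 20.2 CPM (-2.07 ± 0.21). Fibronectin, Fn1, rose from 2723 ± 55.5 to 5693 ± 1028 CPM (1.06 ± 0.12, adjusted p = 0.00025), as did Tgfb1 (0.54 ± 0.09), and 4 genes rose without WGP replicate 2. Without PBS replicates 1 and 3, chosen after the data were seen, 3 fell and 1 rose, and Mgl2 (0.076), Fn1 (0.053) and Mrc1 (0.171) did not pass. Of the 21 genes 2, Chil3 and Mrc1, are also alveolar macrophage markers, and Fn1 is also a classical monocyte marker. Genes of cholesterol efflux and lipid handling had a median of -0.71 (adjusted p = 0.0055; adjusted p = 0.377 with an estimated correlation). Of 21 genes 12 fell and 4 rose over all genes and adjusted over the list alone. Among those that fell were the fatty acid carriers Fabp4 (-1.82 ± 0.11) and Fabp5 (-1.23 ± 0.14) and the scavenger receptor Cd36 (-1.10 ± 0.08). Those that rose were the lipogenic genes Scd2 (0.79 ± 0.09), Acaca (0.38 ± 0.11) and Srebf1 (0.27 ± 0.08) and the nuclear receptor gene Ppard (0.75 ± 0.11). Acaca did not pass without PBS replicate 1, PBS replicate 3 or WGP replicate 3 (0.060 to 0.073), nor Srebf1 without PBS replicate 2, PBS replicate 3 or WGP replicate 3 (0.055 to 0.073). With library sizes alone 2 genes of the list rose, and Acaca (0.069) and Srebf1 (0.143) did not pass. Srebf1 did not pass with upper quartile scaling either (0.065). Outside the cell-type marker lists, 15 of these genes remained, 4 higher and 6 lower, with a median of -0.22. Cholesterol synthesis genes had a median of 0.26 (adjusted p = 0.0050; adjusted p = 0.430 with an estimated correlation). Of 24 genes 4, also adjusted over the list alone, rose, among them Sc5d (0.75 ± 0.13) and Cyp51 (0.42 ± 0.08), and the median was 0.15 without WGP replicate 3 or with library sizes alone.

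Genes of β-glucan receptors and their signalling rose more often than they fell, 11 higher and 3 lower of 21 over all genes and adjusted over the list alone. The median was 0.27 (adjusted p = 0.035; adjusted p = 0.546 with an estimated correlation). Itgam, a subunit of complement receptor 3, which binds β-glucan, rose by 0.66 ± 0.08 (adjusted p = 0.00014). The adaptor gene Card9 rose from 125 ± 5.44 to 198 ± 9.20 CPM (0.66 ± 0.07, adjusted p = 0.00011), Plcg2 from 507 ± 34.0 to 792 ± 28.8 CPM (0.64 ± 0.07) and the kinase gene Lyn from 740 ± 19.3 to 958 ± 19.3 CPM (0.37 ± 0.06). The genes that fell all encode receptors, the lectin Clec4n (-1.84 ± 0.25), Tlr4 (-0.69 ± 0.13) and Tlr2 (-0.52 ± 0.10). Without PBS replicate 1 (adjusted p = 0.062), PBS replicate 3 (0.059) or WGP replicate 3 (0.056) the list did not pass, its median was 0.17 with library sizes alone, and 7 genes rose without PBS replicate 1 or WGP replicate 3. Another gene of it was not analysed here. Clec4e is also a classical monocyte marker, and of the 20 other genes 11 rose and 3 fell. Summed classical monocyte markers rose in the same libraries, from 17922 ± 783 to 31181 ± 1371 CPM. Genes of the NADPH oxidase and of antioxidant defence did not pass as a list (median 0.14, adjusted p = 0.087), though it did with no filter on low counts (0.029), without PBS replicate 2 (0.045) or without WGP replicate 1 (0.044). Of 22 genes 10 rose and 4 fell, or 11 and 5 when adjusted over the list alone. Those that rose included Prdx5 (0.93 ± 0.08), Rac2 (0.75 ± 0.08), the oxidase subunit gene Ncf4 (0.75 ± 0.08) and the glutathione reductase gene Gsr (0.70 ± 0.08). Those that fell were Hmox1 (-0.93 ± 0.16), Srxn1 (-0.57 ± 0.17), Cat (-0.40 ± 0.08) and Prdx1 (-0.35 ± 0.10). Srxn1 and Prdx1 no longer passed without PBS replicate 1 (0.132 and 0.063), PBS replicate 2 (0.067 and 0.073) or WGP replicate 3 (0.083 and 0.078), nor did Srxn1 without WGP replicate 2 (0.085).

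In central metabolism, 9 of 23 glycolysis genes rose and 3 fell over all genes and adjusted over the list alone. The median was 0.21 (adjusted p = 0.034; adjusted p = 0.404 with an estimated correlation and 0.077 without PBS replicate 3). With library sizes alone the median was 0.11, and 8 rose and 4 fell. It was also 0.11 with the Y-linked level as a covariate, chosen after the data were seen, where the list did not pass (0.143). The pyruvate kinase gene Pkm rose from 717 ± 31.8 to 1097 ± 24.3 CPM (0.61 ± 0.07, adjusted p = 0.00012), Eno1 from 240 ± 3.04 to 344 ± 8.55 CPM (0.52 ± 0.06) and Hk3 from 76.5 ± 4.96 to 125 ± 13.5 CPM (0.71 ± 0.09). Aldoc (-1.65 ± 0.19), the lactate transporter gene Slc16a1 (-1.15 ± 0.26) and Pfkfb3 (-0.32 ± 0.11) fell. Summed classical monocyte markers rose in the same libraries, from 17922 ± 783 to 31181 ± 1371 CPM. In the pentose phosphate pathway 5 of 8 genes rose and 1 fell, also adjusted over the list alone. They were Tkt at 0.71 ± 0.06, G6pdx at 0.66 ± 0.08, Pgd at 0.61 ± 0.07, Rpe at 0.45 ± 0.09, Taldo1 at 0.36 ± 0.07 and Prps1 at -0.63 ± 0.18. The list did not pass (median 0.40, adjusted p = 0.054). It passed camera only without WGP replicate 3 (0.042), with upper quartile scaling (0.038) or library sizes alone (0.033) or with no filter on low counts (0.029). The call of Pfkfb3 was lost without PBS replicate 1, PBS replicate 2, WGP replicate 1 or WGP replicate 3 (0.091 to 0.156), and that of Prps1 without PBS replicate 1, PBS replicate 3, WGP replicate 2 or WGP replicate 3 (0.057 to 0.067).

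Of 71 nuclear-encoded genes of the respiratory chain and ATP synthase 16 rose and 1 fell, or 9 and 0 when adjusted over the list alone. They had a median of 0.17 (adjusted p = 0.00039; adjusted p = 0.430 with an estimated correlation). Ndufs8 (0.59 ± 0.08) and Atp5c1 (0.39 ± 0.07) rose, and Atp5b was the gene that fell (-0.21 ± 0.07). Of 82 cytosolic ribosomal protein genes 27 rose and none fell, 30 when adjusted over the list alone. They had a median of 0.16 (adjusted p = 9.7e-07; adjusted p = 0.598 with an estimated correlation) and included Rpsa (0.42 ± 0.07) and Rplp0 (0.36 ± 0.07). With PBS replicate 1 left out, 8 respiratory and 7 ribosomal genes rose, without PBS replicate 2 9 and 9, without WGP replicate 1 9 and 13, and without WGP replicate 3 9 and 10. Without WGP replicate 2, 3 respiratory genes fell. With upper quartile scaling 8 respiratory and 10 ribosomal genes rose. With library sizes alone 6 respiratory genes rose and 4 fell, and 6 ribosomal genes rose and 2 fell, with medians of 0.07 and 0.06. Of 25 genes of the tricarboxylic acid cycle 7 rose and 3 fell, or 8 and 3 when adjusted over the list alone, with Idh1 (0.78 ± 0.08) among those that rose. Suclg2 (-0.62 ± 0.19), Mdh1 (-0.32 ± 0.07) and Aco1 (-0.26 ± 0.08) fell. The list did not pass (median 0.10, turning to -0.002 with library sizes alone, adjusted p = 0.14). With PBS replicate 1 left out, 2 genes of that list rose and 1 fell, without PBS replicate 2 3 rose and 1 fell, without WGP replicate 3 4 rose, and with upper quartile scaling 3 rose and with library sizes alone 2. Leaving out 1 library ended the calls of Atp5b (PBS replicates 1 and 3, WGP replicates 1 and 3, adjusted p of 0.059 to 0.142 without one of them), Suclg2 (PBS replicates 1 and 2, WGP replicate 2, 0.058 to 0.108) and Aco1 (PBS replicates 1 and 2, WGP replicates 1 and 3, 0.083 to 0.121).

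Enzymes and receptors of sphingosine-1-phosphate and ceramide went both ways. Of 30 tested 9 rose and 7 fell, or 10 and 8 when adjusted over the list alone, and 5 rose without PBS replicate 1. The list did not pass (adjusted p = 0.78), with a median of 0.004 that turned negative without PBS replicate 1 or WGP replicate 1 and with upper quartile scaling or library sizes alone, under both of which 5 rose, and a mean of -0.31. The ceramide synthase gene Cers6 (ENSMUSG00000027035, chromosome 2, 68861441 to 69114282) rose by 1.09 ± 0.07 (adjusted p = 9.0e-06) to 437 ± 18.6 CPM and the sphingomyelin synthase gene Sgms2 from 36.4 ± 6.39 to 98.6 ± 14.1 CPM (1.44 ± 0.14). The ceramidase gene Acer2 (-2.27 ± 0.25) and the receptor gene S1pr1 (-0.99 ± 0.13) fell. Of the kinases that make sphingosine-1-phosphate, Sphk2 rose from 61.0 ± 3.17 to 80.1 ± 5.95 CPM (0.39 ± 0.09, adjusted p = 0.0063), and Sphk1 was measured at 0.74 ± 0.11 and 0.20 ± 0.19 CPM and did not pass (-1.85 ± 1.01, adjusted p = 0.19).

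All 13 heat shock genes fell, also adjusted over the list alone, with a median of -1.04 (adjusted p = 5.4e-07; adjusted p = 0.456 with an estimated correlation). Hspb1 fell from 16.1 ± 5.08 to 1.55 ± 0.19 CPM (-3.37 ± 0.28), the chaperonin gene Hspd1 from 133 ± 17.1 to 59.3 ± 4.47 CPM (-1.16 ± 0.10) and Hsp90ab1 from 2537 ± 294 to 1362 ± 39.6 CPM (-0.90 ± 0.09). Immediate-early genes did not pass as a list (median -0.10, adjusted p = 0.15), though 8 of 24 fell, 9 when adjusted over the list alone, and none rose. Without WGP replicate 1, 4 rose and the median was 0.02. Egr2 was at -3.05 ± 0.22 (adjusted p = 0.00021), Jun at -0.87 ± 0.12 and Egr3 at -1.50 ± 0.21. Cell cycle genes were lower, 12 of 39 over all genes and 17 adjusted over the list alone. Without WGP replicate 2, 28 fell with a median of -1.53, against 6 without PBS replicate 1 and 7 without WGP replicate 3, and DESeq2 and limma-voom gave 21 and 22. With the Y-linked level as a covariate 4 fell, and 0 without PBS replicates 1 and 3, where the median was -0.60. The median with all libraries was -0.95 (adjusted p = 3.8e-05; adjusted p = 0.598 with an estimated correlation), among them Stmn1 (-1.84 ± 0.29) and the replication licensing genes Mcm7 (-0.88 ± 0.18) and Mcm6 (-0.84 ± 0.18). Histone transcripts had a median of -1.11 (adjusted p = 0.0029; adjusted p = 0.377 with an estimated correlation). Of 18 genes 3, also adjusted over the list alone, fell, namely Hist1h1c, Hist1h1d and Hist1h2bc, and 5 fell without WGP replicate 3. Genes of amino acid and iron metabolism had a median of -0.45 (adjusted p = 0.034; adjusted p = 0.377 with an estimated correlation). Of 19 genes 9 fell and 2 rose, also adjusted over the list alone. Among those that fell were the ferritin genes Fth1 (-0.81 ± 0.13) and Ftl1 (-0.44 ± 0.07). Slc11a1 (0.36 ± 0.08) and Asl (0.36 ± 0.11) rose, Asl not without PBS replicate 2, PBS replicate 3, WGP replicate 1 or WGP replicate 2 (0.080 to 0.104). Asl also did not pass with library sizes alone (0.133), upper quartile scaling (0.076) or limma-voom with quality weights (0.052). Without PBS replicate 1 (0.056), WGP replicate 2 (0.053) or WGP replicate 3 (0.056) or the filter on low counts (0.057) that list did not pass. The summed alveolar macrophage, epithelial and endothelial markers fell in the same libraries as these groups.

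The remaining lists did not pass camera's test with all libraries. Phagocytic, Fc and scavenger receptors (adjusted p = 0.15) had 4 of 17 higher, Msr1 (1.04 ± 0.10), Fcgr1, Scarb1 (0.75 ± 0.08) and Lrp1 (0.44 ± 0.07), and 6 lower. Lysosomal genes (adjusted p = 0.41) had 6 of 28 higher, among them Npc2 (0.64 ± 0.07), and 10 lower, among them Ctsd (-1.63 ± 0.16) and Cd63 (-2.02 ± 0.23). Adjusted over the list alone these counts were 4 and 6, and 7 and 10. Of 17 complement genes (adjusted p = 0.13) C3 rose from 702 ± 128 to 1635 ± 193 CPM (1.22 ± 0.14, adjusted p = 0.00047). Another 3 fell, Itgax, C5ar1 (-0.90 ± 0.20) and Cd55 (-0.88 ± 0.30), or 1 and 2 when adjusted over the list alone. Without WGP replicate 1, 8 complement genes fell and the list passed (0.019), 5 fell without WGP replicate 3 and 1 without PBS replicate 1, and DESeq2 and limma-voom gave 7 each. The call of C5ar1 was lost without PBS replicate 1, WGP replicate 1 or WGP replicate 2 (0.057 to 0.063). That of Cd55 was lost without PBS replicate 1, PBS replicate 3, WGP replicate 1 or WGP replicate 3 (0.092 to 0.189). Of 19 genes of the mTOR and AKT pathway (adjusted p = 0.087) 3 rose, Pik3cd (0.80 ± 0.09), Hif1a (0.41 ± 0.10) and Akt1 (0.26 ± 0.07). Hif1a and Akt1 did not pass without PBS replicate 1 (0.061 and 0.074) or with library sizes alone (0.051 and 0.094), under which the list's median went from 0.10 to below 0, 1 gene rose and 2 fell. That list passed with no filter on low counts (0.045) or without WGP replicate 2 (0.041). Of 31 histone-modifying enzymes (adjusted p = 0.14) 5 rose, Kdm6b (0.65 ± 0.14), Kat2b (0.46 ± 0.08), Tet2 (0.38 ± 0.10), Kat5 (0.31 ± 0.09) and Ep300 (0.28 ± 0.07). A further 3 fell, Sirt1 (-0.48 ± 0.13) and the X-linked Kdm6a (-0.41 ± 0.13) and Kdm5c (-0.40 ± 0.11). With library sizes alone 3 rose and 5 fell, and Tet2 (0.056) and Kat5 (0.124) did not pass. Kat5 did not pass with upper quartile scaling either (0.068). Leaving out 1 library ended the calls of Ep300 (PBS replicate 1, 0.056), Kdm6b (PBS replicate 3, 0.051) and Sirt1 (PBS replicate 2, 0.072, WGP replicate 2, 0.057, or WGP replicate 3, 0.054). It also ended those of Tet2 (PBS replicate 1, WGP replicate 1 or WGP replicate 3, 0.059 to 0.088), Kat5 (PBS replicate 1, PBS replicate 2 or WGP replicate 1, 0.078 to 0.088), Kdm5c (WGP replicate 1, 0.059) and Kdm6a (any library but PBS replicate 2, 0.054 to 0.110). For these 2 lists the counts adjusted over the list alone were the same.

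Among adhesion, migration and matrix genes 7 of 25 rose, with Itga4 at 1.09 ± 0.09 besides Ccr2 and Itgam. A total of 4 fell, the matrix metalloproteinase genes Mmp12 (-2.77 ± 0.20) and Mmp13 (-3.20 ± 0.41), Timp2 (-0.80 ± 0.21) and Itgb1 (-0.23 ± 0.06), also adjusted over the list alone (adjusted p = 0.52). A total of 4 rose without PBS replicate 1. The median of 0.06, which turned negative without PBS replicate 2 or 3 and with limma-voom or library sizes alone, differed in sign from the mean of -0.19. Of 11 mitochondrial fission genes, also adjusted over the list alone, 3 rose, Mtfr1 (0.52 ± 0.14), Mtfr1l (0.31 ± 0.09) and Fis1 (0.28 ± 0.07), and 2 fell, Spire1 (-1.86 ± 0.16) and Dnm1l, the fission GTPase (-0.45 ± 0.12). Of 8 fusion genes 1 rose, Afg3l2 (0.52 ± 0.10), with adjusted p of 0.59 and 0.52 for these lists. The fission list's median of 0.08 and mean of -0.16 differed in sign. Both medians turned negative with library sizes alone, that of the fusion list also with upper quartile scaling and without PBS replicate 2 or 3. With library sizes alone none of the 3 fission genes that rose passed (Mtfr1 0.052, Fis1 0.063 and Mtfr1l 0.113), and without PBS replicate 3, 2 fusion genes rose. Without PBS replicate 1 Fis1 no longer passed (0.055). Without PBS replicate 2 or WGP replicate 3 neither Mtfr1 (0.054 and 0.087) nor Dnm1l (0.058 and 0.062) passed, and without PBS replicate 3 Mtfr1 did not (0.063). The same held for Mtfr1l without PBS replicate 2, PBS replicate 3, WGP replicate 1 or WGP replicate 3 (0.066 to 0.069), for Timp2 without any PBS library or WGP replicate 2 (0.058 to 0.120) and for Itgb1 without WGP replicate 1 (0.068) or 3 (0.052). Of eosinophil, mast cell and basophil genes only 2 were tested, too few for a list test. Kit fell (-1.65 ± 0.48, adjusted p = 0.039), not so without PBS replicate 1, 2 or 3 or WGP replicate 3 (0.070 to 0.127), while Ccr3 did not pass. The 4 tested genes of the sex-linked list, all Y-linked, did not pass either, over all genes or adjusted over the list alone (list adjusted p = 0.15). They varied within the PBS group, and 2 rose without PBS replicate 3 or with limma-voom. Their summed levels were 112, 179 and 9.79 CPM in PBS replicates 1, 2 and 3 against 227, 205 and 220 CPM in the WGP libraries.

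Without PBS replicates 1 and 3, chosen after the data were seen, 82 of the 257 named genes no longer passed, in a fit with 1 PBS library. In that fit 7 of the alveolar macrophage genes fell, 1 of the interstitial macrophage genes, 7 chemokine, 5 amino acid and iron and 8 lipid handling genes. Type I interferon-stimulated genes rose in 15 cases, interferon gamma-responsive genes in 1, β-glucan receptor and signalling genes in 5, NADPH oxidase and antioxidant genes in 6, and pentose phosphate genes in 3. Respiratory genes rose in 4 cases, ribosomal protein genes in 8, tricarboxylic acid cycle genes in 3 and cholesterol synthesis genes in 1. Among histone-modifying enzymes 1 rose and 1 fell, among sphingosine-1-phosphate and ceramide genes 3 rose and 4 fell, among NF-kB targets 3 rose and 3 fell, and 3 lysosomal genes rose. Lists that no longer passed there included interstitial macrophage markers (0.311), β-glucan receptors and signalling (0.285), glycolysis (0.231) and amino acid and iron metabolism (0.070).

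**Figure D3:**
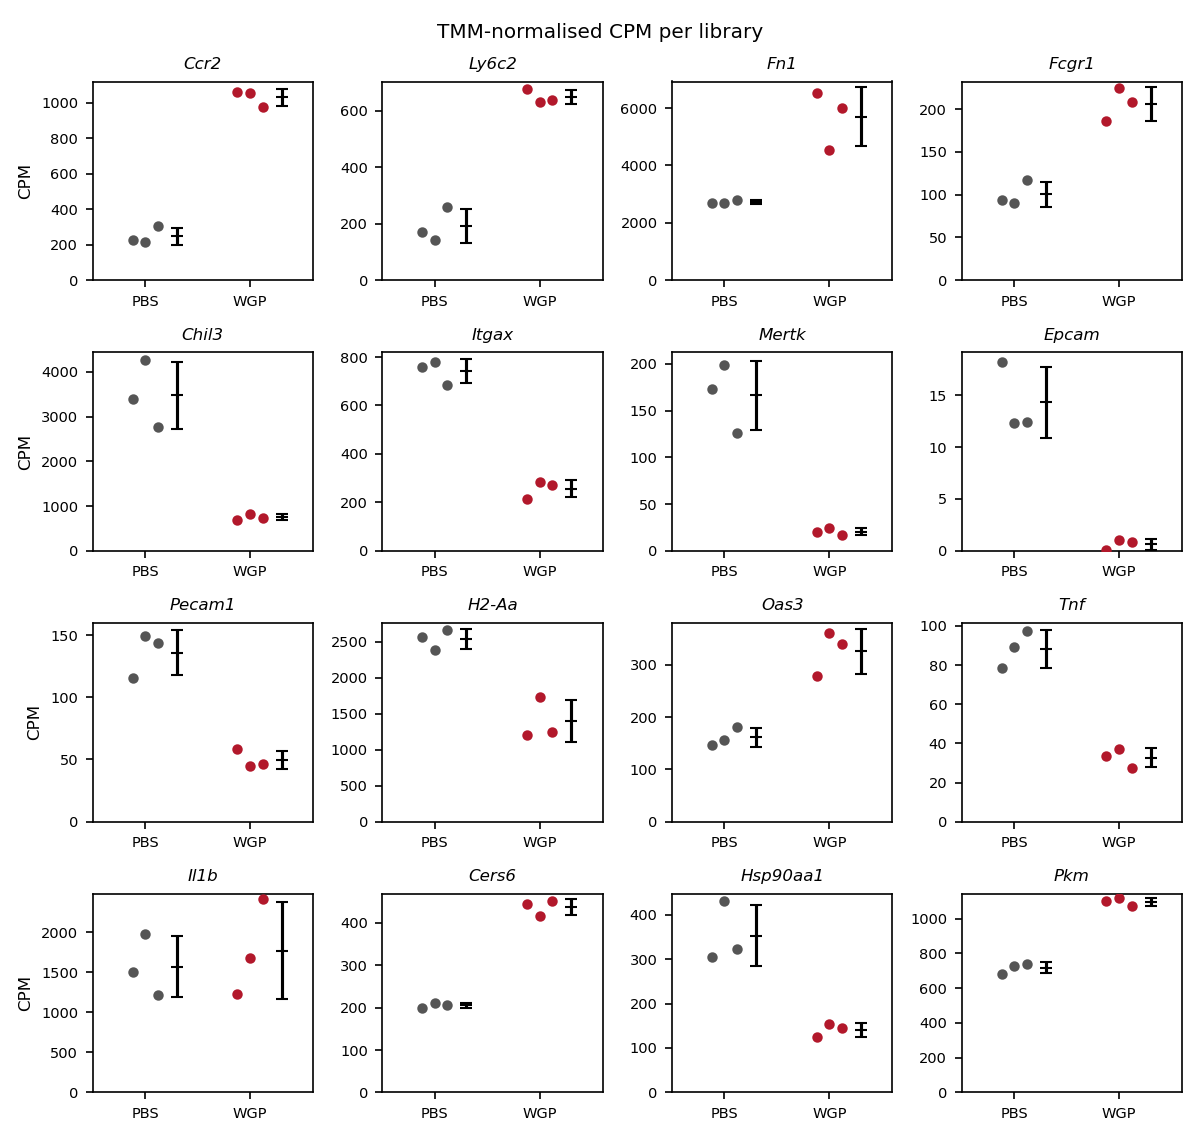
TMM-normalised CPM of 16 genes in each of the 3 PBS (grey) and 3 WGP (red) libraries, on linear axes that start at 0, with the group mean and SD in black beside the points. The WGP libraries lie wholly above or below the PBS libraries in every panel except that of Il1b, whose groups overlap at 1570 ± 383 and 1774 ± 604 CPM.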

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

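The alternatives on the Y-linked level, on length and GC content and on thinning were chosen after the data were seen, and the others before. No changed gene was called in the other direction under any alternative. Against 3809 changed genes (1874 higher and 1935 lower), a 2-fold minimum left 1297 (163 and 1134), by construction, and library sizes alone as the scaling gave 1236 higher genes, where the median of all genes shifted to -0.12. Leaving out 1 library gave 2491 to 3717 changed genes, 1202 to 1753 higher and 1289 to 1964 lower, the lowest without PBS replicate 1. Leaving out PBS replicates 1 and 3 gave 1820 (993 and 827), with 1 PBS library against 3, so the spread came from the WGP libraries alone. Why leaving out PBS replicate 1 lowered the counts most was not tested. The remaining settings gave 3058 (Y-linked covariate) to 4871 (adjusted p under 0.1) genes. With the replicate number as a block 3185 genes changed, 1584 higher and 1601 lower, and 22 lists passed. Same-numbered libraries did not deviate together from their group means (r = -0.063, -0.081 and -0.046, against -0.043 to 0.112 for libraries of different number). These values give no sign that the numbers pair the libraries, but with 3 libraries per group they cannot exclude it. Of 257 named genes over these settings, 4775 of 5138 values kept their side of the threshold, 302 lost it, 61 gained it and 0 turned. Of the 23 lists past camera, 17 stayed past it in all 16 refits of the genes. The other 6 (interstitial macrophage, dendritic cell, MHC class II, β-glucan receptor, glycolysis, and amino acid and iron genes) lost the call with the Y-linked covariate and without PBS replicates 1 and 3. With an estimated correlation 0 passed, and what ended these calls was not tested. The depth of 18254678 to 20346517 counts limits genes under 1 CPM, such as Sphk1.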

Other observations

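Clock genes, a group chosen after its values were seen, changed in part. Of 15 tested, 7 fell, 1 rose and 7 did not pass. Those that fell were the repressors Nr1d1, from 25.9 ± 2.04 to 4.08 ± 0.46 CPM (mean ± SD, n = 3; log2 fold change -2.66 ± 0.17, edgeR adjusted p = 9.0e-06), Nr1d2 (-0.68 ± 0.14), Bhlhe41 (-3.29 ± 0.37) and Bhlhe40 (-0.93 ± 0.09), Per2 (-1.58 ± 0.25), Per3 (-1.31 ± 0.40) and Tef (-0.62 ± 0.13). Nfil3 rose (0.42 ± 0.08), while Arntl (0.17 ± 0.13, adjusted p = 0.34), Clock (0.01 ± 0.09) and Per1 (0.19 ± 0.12) did not pass. Per3 no longer passed without PBS replicate 1, PBS replicate 3 or WGP replicate 1 (0.061 to 0.114). The times of day at which the lungs were taken are not given in the sources used here, and no explanation was tested. Fkbp5 and Zbtb16, also chosen after their values were seen, fell from 355 ± 77.0 to 33.2 ± 3.71 CPM (-3.42 ± 0.19, adjusted p = 5.6e-05) and from means of 72.3 to 33.4 CPM (-1.12 ± 0.13, adjusted p = 0.00019).

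Some transcripts of the nonclassical monocyte list were abundant in both groups. Its 14 tested genes summed to 10988 ± 963 CPM after PBS and 10435 ± 1065 CPM after WGP. Nr4a1 was at 3658 ± 348 and 3432 ± 494 CPM, Ace at 2237 ± 196 and 1806 ± 259 CPM and Itgal at 2039 ± 186 and 2133 ± 142 CPM after PBS and WGP, and none of these 3 genes passed the test. Nr4a1 is also an immediate-early gene. The most abundant interstitial macrophage markers were Apoe, at 2637 ± 345 and 1700 ± 172 CPM, and Csf1r, at 2357 ± 199 and 2965 ± 23.2 CPM. Nr4a1 and Itgal were chosen after their values were seen.

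Of the tests that follow, those of dilution, of a varying alveolar macrophage share and of a wrong label on PBS replicate 3 were chosen after the result was seen. Alveolar macrophage markers fell while classical monocyte markers rose. The alveolar median lay -2.95 (95% bootstrap interval over members, not libraries, -3.62 to -1.17) from the interstitial median. Added monocytes that dilute the other cells alike predict 0, but only if they lack the transcripts of both lists. Of the interstitial markers 3 rose, Fcgr1, Cx3cr1 and Csf1r, so the comparison cannot decide on dilution. Dilution stays open, as do a smaller share of alveolar macrophages in the WGP libraries and lower transcription of these genes within the sorted cells. WGP replicate 1 was the lowest WGP library for 18 of the 20 members, but it also lay furthest from the PBS libraries on the first principal component (73.0 against 32.9 and 46.3), so genes that fell would tend to be lowest there whatever the cause.

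Changes of at least 2-fold were decreases 6.96 times as often as increases. The 3 other scalings gave ratios of 7.07, 9.86 and 12.0 (size factors of DESeq2, upper quartile and library sizes alone). Each moved the median log2 fold change of all genes lower, to -0.023, -0.081 and -0.123 from -0.021. Such shifts favour decreases, so these scalings could not give the predicted ratio under 1.5 and cannot decide on the scaling. Depth (6.83 after thinning to 18254678 counts) and trends with length and GC content (7.03 after their removal) are argued against, as each predicted a ratio under 1.5. It was lower, 4.18 and 3.01, with the Y-linked level as a covariate and without PBS replicates 1 and 3, and 4.88 without PBS replicate 3. A cell population whose share fell and lower transcription after WGP stay open: of the genes outside the alveolar list that were at least 2-fold lower, 52.3% had WGP replicate 1 as their lowest WGP library, but its distance from the PBS libraries favours this for genes chosen as lower whatever the cause.

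Y-linked transcripts summed to 112, 179 and 9.79 CPM in PBS replicates 1, 2 and 3 and to 227, 205 and 220 CPM in WGP replicates 1, 2 and 3. If sex of the mice caused the calls at large, under 10% of the changed genes were predicted to stay called with the Y-linked level as a covariate. In that fit 74.6% were still called in the same direction. The share was lower without PBS replicates 1 and 3, in a fit with 1 PBS library. Every PBS library lay below every WGP library in this level, so the covariate cannot fully part sex from WGP and does not exclude sex. PBS replicate 3, with the lowest level, had the highest mean r with the WGP libraries, 0.945 against 0.935 and 0.934 for PBS replicates 1 and 2. A WGP library wrongly labelled as PBS replicate 3 is argued against, because its mean r with the other PBS libraries exceeded that with the WGP libraries by 0.0346, against a range of 0.00657 within the PBS group. The sex of the mice, or mixing of RNA from both sexes, stays open for the calls at large and for single genes. The X-linked Kdm6a had a log2 fold change of -0.41 with and -0.23 without PBS replicate 3.

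Among the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 3809 changed genes and the highest of the others gave 0, and 10 splits are too few for a share under 0.05. Each other split mixes PBS and WGP libraries on both sides, so the difference between the groups widens its spread. The 0 therefore does not measure how many genes would be called by chance.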
